A study of Citrus sinensis with 12 samples.

How the data were processed

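The series holds 12 RNA-seq libraries from roots of Citrus sinensis seedlings, 3 for each combination of pH 3 or 4.8 with 0.5 or 300 µM CuCl2, after 17 weeks of treatment. Per the labels' protocols, equal amounts of frozen root from 4 seedlings in separate pots made up each replicate, and libraries were made from 1 µg of RNA with the NEBNext Ultra RNA kit. Groups were taken from the treatment label of each sample. The titles of the control samples at pH 4.8 give 5 µM copper where the treatment label gives 0.5 µM, and 0.5 µM was used, as in the series' design text.

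The authors deposited a table per library with FPKM values to 2 decimals, the position and the strand of 20122 genes, the same genes in every table. Per the submitters' processing notes, fastp 0.19.3, HISAT2 2.1.0, featureCounts 1.6.2, StringTie 1.3.4d and DESeq2 1.22.1 were used, with no role or order stated. The genome build, the annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here, so values of near-identical gene copies and of overlapping genes are uncertain. Each listed gene reached at least 0.18 FPKM in at least 1 library, and 19788 genes were above 0 in all 12, so genes without reads had been left out of the tables before deposit or were never listed.

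No counts were in the tables, whereas the design fixed beforehand put a count test first. Its stated alternative for tables without counts was used as the main test. FPKM was transformed as log2(FPKM + 1), with a pseudocount of 1. Genes with a mean of at least 1 FPKM in at least 1 group were tested, which kept 19204 and left out 918. A model with a mean for each of the 4 groups was fitted to all 12 libraries in limma 3.58.1 (R 4.3.3) with a trend of the variance on the mean level. The tests were copper at pH 3, copper at pH 4.8, low pH at 0.5 µM copper, low pH at 300 µM copper and the copper by pH interaction. Adjusted p-values are Benjamini-Hochberg values over the tested genes within each test, two-sided, with a threshold of 0.05. Fold changes on this scale understate the change of genes near 1 FPKM or below. The fit was tested on simulated data for copper at pH 3 over 19204 genes: 34% of genes changed by 0.5 log2 units were called, 90% of those raised by 1, 82% of those lowered by 1 and 100% of those raised by 2, and 8 of 161 calls were false. The simulation changed 50 genes per size, none at the lowest levels, with equal noise in all groups. In the data 36.3% of genes were called in this test, and the median SD was 0.115 to 0.179 by group. These shares therefore need not hold for the data.

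Depth was recovered from the FPKM values. In a library, the FPKM of genes shorter than 900 bp and under 6 FPKM were compared with whole multiples of the value of 1 fragment over a range of possible depths. The best depth lay between 17710000 and 22780000 fragments, with a periodicity score of 0.65 to 0.69 on a scale that ends at 1, against at most 0.09 at depths away from it and below its multiples. At that depth 76.1% to 79.0% of 882 to 958 values per library came within 0.15 of a whole fragment, where chance gives 30%. As this share is far from complete, no counts were rebuilt and no count test was run. The procedure was checked on simulated data over 20122 genes and returned the true depth within rounding. Before rounding, the simulated values were whole multiples at the same gene lengths that the procedure used. The check therefore does not cover lengths that differ from those behind the deposited FPKM. The value of 3 fragments on a gene of 1 kb, 0.132 to 0.169 FPKM, was taken as the floor of a library. The 10 most abundant genes held 4.56% to 6.51% of the summed FPKM.

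Genes named in the text follow a rule fixed before the data were examined. For identifiers without names, the rule takes in each test the 2 largest rises and the 2 largest falls among called genes with a mean of at least 5 FPKM in the higher group and, outside the interaction, no overlap between the 3 libraries of the groups compared. Loci without an annotated identifier, called assembled loci here, are given by position instead of identifier. None of the 20122 identifiers was found in the RefSeq gene table given for the species (assembly DVS_A1.0), whose coordinates were not used. The 36 gene lists fixed beforehand (such as copper transport, metal chelation and antioxidant enzymes) select members by description, so they stayed empty, and the planned camera and fry tests of them were not run. Levels were classed by the mean over all libraries, as abundant from 100 FPKM and as low under 5 FPKM. Overlaps of called genes were set against the number that independent lists of the same sizes would share, per direction. All tests share a single spread estimate per gene, so the lists are not independent even without a common response. Noise-corrected sizes are root mean square differences after subtracting the variance that the spread among libraries gives. For tests that share control libraries, unchanged groups were simulated against those libraries 100 times.

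Alternatives chosen before the data were examined were a pseudocount of 0.1 without the variance trend, quantile normalization, no filter, a filter of at least 5 FPKM in at least 3 libraries, an adjusted p under 0.01, a minimum log2 difference of 1, the replicate number as a block, fits to only the groups compared, and each library left out in turn. Median scaling, and quantile normalization for the overlap, were added after seeing the data, as were the rules for genes particular to a group and for neighbouring genes. Neighbouring genes are adjacent tested genes in the order of the files' coordinates, and their joint changes were set against 1000 shuffles of gene order. The 20 genes at 0.5 FPKM or less in a single group were set against 10000 random sets of genes matched on level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.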

Results

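Roots of sweet orange (Citrus sinensis) seedlings were profiled by RNA sequencing after 17 weeks at pH 3 or pH 4.8, each combined with 0.5 or 300 µM CuCl2. Copper is a micronutrient of plants that is toxic in excess. The labels call pH 4.8 and 0.5 µM the control levels, and the title of the series presents the work as a study of how a higher pH eases copper toxicity in these roots. Each of the 4 groups had 3 libraries, and each library came from a pool of 4 seedlings. The deposited tables list FPKM (fragments per kilobase of gene, scaled to the depth of the library) for 20122 genes in all 12 libraries. Between 17710000 and 22780000 fragments stood behind each library, as recovered from the steps between low FPKM values. At that depth 3 fragments on a gene of 1 kb were worth 0.132 to 0.169 FPKM, a floor that covers counting error only.

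The listed genes comprised 16013 identifiers placed on 9 chromosomes of the authors' annotation, 2717 identifiers on unplaced sequence (chromosome Un, identifiers starting with orange1.1t) and 1392 loci without an annotated identifier, called assembled loci here and given by position. The files do not pair the identifiers with gene names or functions, and 0 of them were found in the RefSeq gene table used here. Genes are therefore given by identifier and position, and the 36 functional gene lists fixed beforehand could not be filled. The genome build behind the coordinates, and the exon structure at each position, are not given in the sources used here.

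All differences below are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, over 19204 tested genes. These p-values measure the spread among pools of seedlings. Changes of at least 2-fold mean differences of at least 1 on that scale, and their number depends on the pseudocount.

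Libraries of a group lay together and apart from the other groups. The first principal component held 45.0% of the variance and placed the pH 4.8 libraries at 0.5 µM copper at -56.2 to -48.4, the pH 3 libraries at 0.5 µM at -27.3 to -18.6, and the libraries of both copper-treated groups at 30.0 to 44.3. The second component held 29.8% and set the copper-treated groups apart by pH, at 34.7 to 42.2 for pH 3 and -48.8 to -43.9 for pH 4.8. Across genes, libraries of the same group correlated at r = 0.988 to 0.991 in 3 groups and at 0.973 to 0.987 in the pH 3 group with 300 µM copper, where the median SD of a gene was 0.179 log2 units against 0.115 to 0.126 in the other groups.

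**Figure D1:**
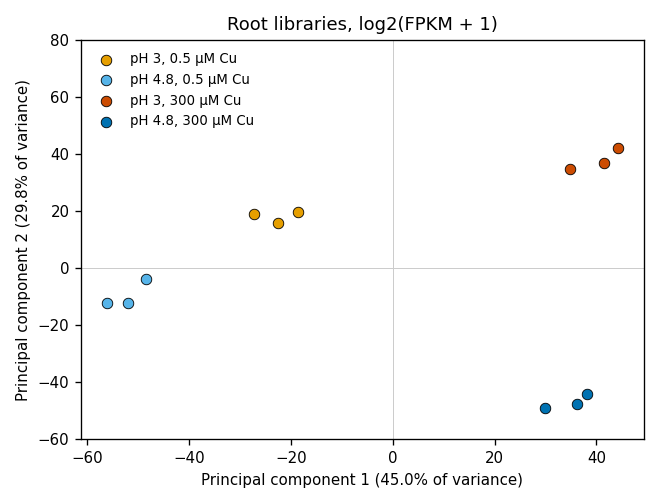
Positions of the 12 root libraries on the first and second principal components of log2(FPKM + 1), with the share of variance in percent on each axis and 1 point per library. The copper-treated groups lie at 30.0 to 44.3 on the first component and part by pH on the second, at 34.7 to 42.2 for pH 3 and -48.8 to -43.9 for pH 4.8.

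The first comparison asked what 300 µM copper changed in roots kept at pH 3. The assembled locus on chromosome 3 from 767533 to 768050 rose from 1.97 ± 2.17 to 544 ± 183 FPKM (SD, n = 3 in each group), a difference of 7.72 (SE 0.78, limma adjusted p = 9.2e-06). Cs5g25760 on chromosome 5 (28609629 to 28610819) rose from 0.577 ± 0.329 to 169 ± 41.5 FPKM, a difference of 6.75 (SE 0.29, limma adjusted p = 3e-08). The largest falls were at a pair of assembled loci on unplaced sequence. At the locus from 81453201 to 81453500 FPKM was 9.32, 24.17 and 17.46 at 0.5 µM and 0.00, 0.15 and 0.78 at 300 µM, a difference of -3.73 (SE 0.66, limma adjusted p = 0.00074) that became -5.83 with a pseudocount of 0.1, and at the locus from 22181072 to 22184003 the mean fell from 67.7 ± 34.7 to 5.14 ± 0.950 FPKM, a difference of -3.33 (SE 0.73, limma adjusted p = 0.003). Neither of these loci was stable among control pools: at pH 4.8 and 0.5 µM copper, replicate 3 had 0.59 FPKM at the former and 3.49 at the latter, against 9.76 to 17.50 and 36.35 to 61.38 in the other replicates.

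Copper at pH 3 changed 6972 genes, 36.3% of those tested. Of these, 3962 rose and 3010 fell. Among changes of at least 2-fold, 899 genes rose and 334 fell, and among changes of at least 4-fold 149 rose and 25 fell. With a pseudocount of 0.1, 1389 rose and 554 fell by at least 2-fold. Of the 1132 abundant genes, with a mean of at least 100 FPKM over all libraries, 220 rose, 439 fell and 473 were not called. Of the 6963 genes with a mean under 5 FPKM, 1473 rose, 594 fell and 4896 were not called. The libraries at pH 3 with 300 µM copper also had fewer genes listed at 0, 8 to 15 against 41 to 118 in the 9 other libraries. Whether this shift at the low end has a technical source was not tested. The same libraries enter low pH at 300 µM copper and the interaction. The larger side among the called genes of each class and of the 2-fold set held under quantile normalization and median scaling. The split of all calls did not: median scaling, chosen after seeing the data, gave 3148 genes higher and 4242 lower (42.6% higher against 56.8%), so small rises cannot be separated from the choice of scale.

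**Figure D2:**
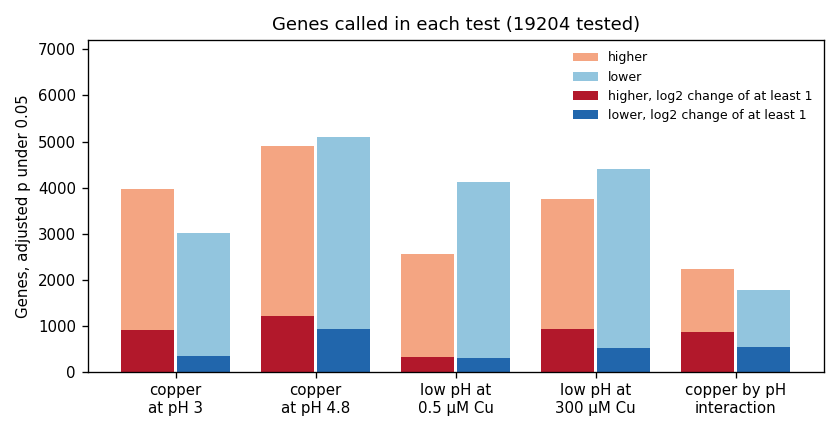
Numbers of genes called higher (red tones) or lower (blue tones) at a limma adjusted p under 0.05 in the 4 comparisons between groups and in the copper by pH interaction, of 19204 tested; darker bars, drawn from 0 in front, count changes of at least 1 on the log2(FPKM + 1) scale. Copper at pH 4.8 gave the most calls, 9988, and low pH at 0.5 µM copper the fewest of the comparisons between groups, 6674. In fits to only the groups compared, copper at pH 4.8 still gave the most, 10500, but copper at pH 3 gave the fewest, 5644.

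The same treatment at pH 4.8 was the copper comparison at the control pH. Cs8g15220 on chromosome 8 (18356028 to 18361843) rose from 0.703 ± 0.189 to 72.9 ± 3.35 FPKM (SD, n = 3 in each group), a difference of 5.44 (SE 0.16, limma adjusted p = 3.4e-10). Cs5g06570 on chromosome 5 (4064768 to 4066699) rose from 0.773 ± 0.320 to 66.7 ± 6.25 FPKM, a difference of 5.27 (SE 0.20, limma adjusted p = 1.8e-09). The gene orange1.1t05521, of 176 bp on unplaced sequence (87539307 to 87539482), was at 235.43, 208.22 and 487.49 FPKM at 0.5 µM copper and was listed at 0 in each of the 3 libraries at 300 µM (limma adjusted p = 3.7e-09), so no fold change is given. Cs2g06910 on chromosome 2 (4045764 to 4046409) fell from 123 ± 47.6 FPKM to 0.00, 0.10 and 1.32 FPKM in the 3 copper-treated libraries, a difference of -6.43 (SE 0.37, limma adjusted p = 2.8e-08) that became -8.59 with a pseudocount of 0.1.

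At pH 4.8 copper changed 9988 genes, 52% of those tested, with 4892 higher and 5096 lower. Changes of at least 2-fold comprised 1217 rises and 919 falls, and changes of at least 4-fold 191 rises and 171 falls. With a pseudocount of 0.1 there were 1831 rises and 1365 falls of at least 2-fold. Of the 1132 abundant genes, 307 rose and 518 fell. In the class under 5 FPKM, 1606 genes rose and 1368 fell. This majority turned under quantile normalization (1407 higher, 1467 lower) and median scaling (1475 higher, 1485 lower). Assembled loci were called less often than annotated genes on chromosomes, 46.6% of 1321 against 52.9% of 15316, a difference that was not itself tested. The root mean square difference, after subtracting the part that spread among libraries gives, was 0.682 log2 units at pH 4.8 and 0.531 at pH 3.

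The next comparison asked how the copper responses at both pH values overlapped, which no shared library links. Copper raised 2560 genes at both pH values, where lists of these sizes drawn independently would share 1009, and lowered 2020 at both, against 799. In opposite directions went 402 genes, against 1818 for independent lists: 254 rose at pH 3 and fell at pH 4.8, and 148 did the reverse. Both tests share the spread estimate of each gene. Of abundant genes, 58.2% were called at pH 3 and 72.9% at pH 4.8, against 29.7% and 42.7% under 5 FPKM. This alone would raise overlaps in either direction above those of independent lists. Cs8g15220 and Cs5g06570 were among those that rose at both, by 2.92 and 3.17 at pH 3. Across genes, which are not independent replicates, the copper differences at both pH values correlated at r = 0.51 and Spearman's rho = 0.60. In all, 4580 genes were shared in direction. Median scaling, chosen after seeing the data, gave 4846 such genes, 4037 of them among the 4580, with 2017 higher and 2829 lower, so the larger side of the shared set depended on the scale.

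**Figure D3:**
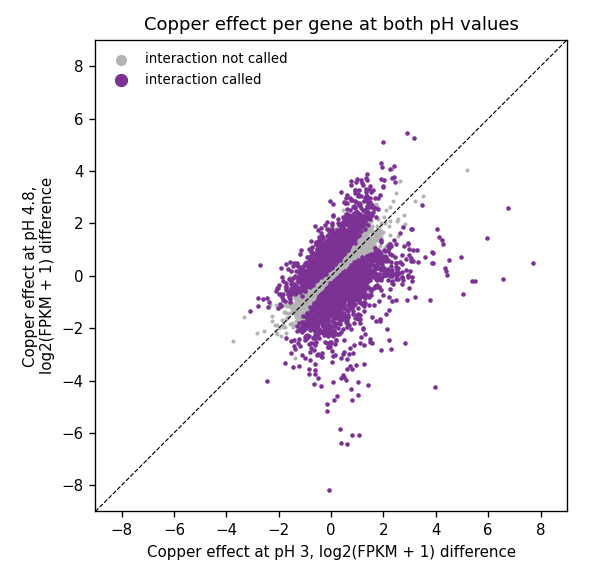
Copper difference of each of 19204 genes at pH 3 (horizontal) and pH 4.8 (vertical), both as differences of mean log2(FPKM + 1), with equal axes and the dashed line of equal change. Purple points are the 3991 genes whose copper difference itself differed between the pH values in limma, and grey points the rest; the correlation across genes is 0.51.

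Whether copper acted differently at the pH values was tested as an interaction, the copper difference at pH 3 minus that at pH 4.8. Cs4g02690 on chromosome 4 (1254521 to 1255539) showed the largest value on this scale: copper raised it from 14.6 ± 7.21 to 224 ± 44.1 FPKM at pH 3 and lowered it from 60.4 ± 14.3 to 2.18 ± 0.324 at pH 4.8 (SD, n = 3 in each group), an interaction of 8.21 (SE 0.42, limma adjusted p = 1.8e-07). The gene orange1.1t05521 was at 338.37, 146.59 and 365.99 FPKM at pH 3 with 300 µM copper, while it was listed at 0 in all 3 libraries at pH 4.8 with 300 µM (limma adjusted p = 5.3e-07). On the other side, Cs1g19920 on chromosome 1 (23077109 to 23077600) fell under copper at pH 3, from 37.6 ± 4.34 to 5.10 ± 2.27 FPKM, and stood at 5.72 ± 1.09 and 8.21 ± 2.68 FPKM without and with copper at pH 4.8, an interaction of -3.15 (SE 0.34, limma adjusted p = 3.7e-05). Cs7g01050 on chromosome 7 (36794 to 37597) rose at both pH values, from 55.4 ± 14.2 to 223 ± 57.2 FPKM at pH 3 and from 7.42 ± 1.62 to 288 ± 19.7 FPKM at pH 4.8, an interaction of -3.12 (SE 0.29, limma adjusted p = 1.1e-05).

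The interaction was called for 3991 genes, 20.8% of those tested, with 2225 values above 0 and 1766 below. This majority turned under quantile normalization (1922 above, 2068 below) and median scaling (1903 above, 2000 below). The copper difference was larger in size at pH 4.8 for 2726 of them (68.3%) and at pH 3 for 1265. By their calls at each pH, 1697 were called at pH 4.8 alone, 824 at pH 3 alone, 1030 at both in the same direction, 402 at both in opposite directions and 38 at neither. Of the 1030, 797 changed more at pH 4.8 and 233 more at pH 3. Genes under 5 FPKM had 768 interaction values above 0 and 376 below, and abundant genes 148 above and 206 below, and these sides held under quantile normalization and median scaling.

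Some genes set a single group apart from the rest. By a rule chosen after seeing the data, a gene was particular to a group if each of its 3 libraries was at least 4-fold above, or at least 4-fold below, each of the 9 other libraries in FPKM, with a mean of at least 5 FPKM on the higher side. In the pH 3 group with 300 µM copper 62 genes stood above and 0 below, and in the pH 4.8 group with 300 µM copper 0 stood above and 79 below. At 0.5 µM copper the numbers were 1 above and 8 below at pH 4.8, and 0 above and 1 below at pH 3. Each of the 216 other sets of 3 libraries gave 0 in both directions. As each of these sets mixes groups, replicates of its members remain among the 9 other libraries. A count of 0 was therefore close to fixed beforehand and gives no measure of chance. At pH 4.8 with 300 µM copper, 20 genes were at 0.5 FPKM or less while all 9 other libraries had at least 5 FPKM of each (5.68 at the lowest), and no other group had such a gene. One of them was orange1.1t05521. The mean of the 20 was 0.05, 0.06 and 0.21 FPKM in the 3 libraries of that group and 23.18 to 59.08 FPKM in the others.

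**Figure D4:**
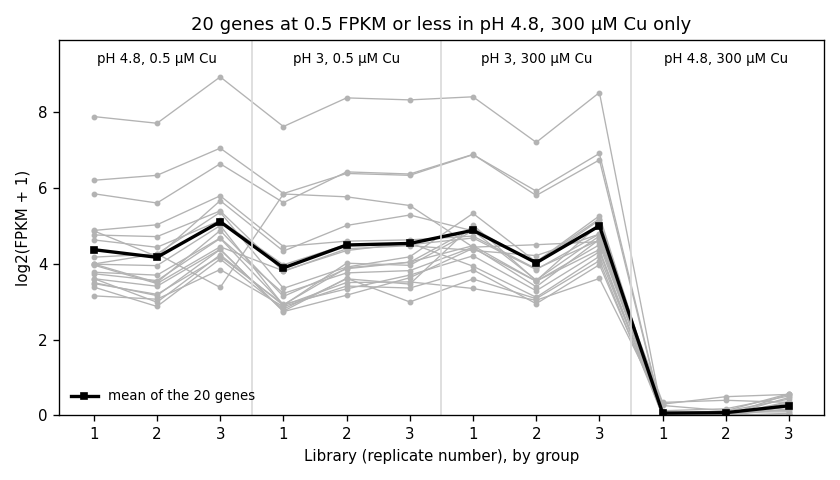
Levels, as log2(FPKM + 1), of the 20 genes at 0.5 FPKM or less in every library at pH 4.8 with 300 µM copper, in each of the 12 libraries by group; grey lines join the values of a gene and the black line their mean over genes. Lines join separate pools and show no order in time. In the 9 other libraries the values range from 5.68 to 487.5 FPKM.

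Low pH was first compared with the control pH at 0.5 µM copper. Cs7g01050 was at 55.4 ± 14.2 FPKM at pH 3 and 7.42 ± 1.62 at pH 4.8 (SD, n = 3 in each group), a difference of 2.73 (SE 0.20, limma adjusted p = 4.3e-06). Cs1g19920 was at 37.6 ± 4.34 FPKM at pH 3 and 5.72 ± 1.09 at pH 4.8, a difference of 2.53 (SE 0.24, limma adjusted p = 1.9e-05). Lower at pH 3 were the assembled locus on unplaced sequence from 7624520 to 7625182, at 3.70 ± 1.31 against 22.4 ± 3.95 FPKM (-2.34, SE 0.32, limma adjusted p = 0.00019), and Cs1g26375 on chromosome 1 (28437185 to 28439516), at 0.267 ± 0.153 against 5.52 ± 1.88 FPKM (-2.33, SE 0.23, limma adjusted p = 2.1e-05). The size for Cs1g26375 rests on values near the floor and became -3.99 with a pseudocount of 0.1.

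Low pH at 0.5 µM copper changed 6674 genes, 34.8% of those tested, with 2563 higher and 4111 lower at pH 3. By at least 2-fold 330 genes rose and 307 fell, and by at least 4-fold 15 rose and 12 fell. The 2-fold numbers became 645 and 653 with a pseudocount of 0.1, 368 and 250 under quantile normalization, and 389 and 257 under median scaling, so neither their size nor their side was fixed. Of the 6963 genes under 5 FPKM, 1217 were lower at pH 3, 537 higher and 5209 not called, and the lower side was also the larger under both other scalings. Abundant genes numbered 263 higher and 367 lower, a majority that turned under quantile normalization (334 higher, 307 lower) and median scaling (312 higher, 295 lower). Median scaling, chosen after seeing the data, evened the split of all calls to 3216 higher and 3287 lower (49.5% higher against 38.4%).

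Low pH was then compared with the control pH at 300 µM copper. The assembled locus on chromosome 3 from 767533 to 768050 was at 544 ± 183 FPKM at pH 3 and 3.28 ± 1.74 at pH 4.8 (SD, n = 3 in each group), a difference of 7.03 (SE 0.78, limma adjusted p = 1.5e-05). The gene orange1.1t05521 was at 146.59 to 365.99 FPKM at pH 3 and listed at 0 in all 3 libraries at pH 4.8 (limma adjusted p = 6.8e-09). Cs2g31160 on chromosome 2 (30493281 to 30494670) was lower at pH 3, 91.8 ± 19.3 against 491 ± 23.7 FPKM, a difference of -2.42 (SE 0.16, limma adjusted p = 1.9e-07). Cs2g14920 on chromosome 2 (11821833 to 11823946) was at 8.65 ± 3.62 FPKM at pH 3 and 42.3 ± 3.48 at pH 4.8, a difference of -2.23 (SE 0.21, limma adjusted p = 3.6e-06), close to its difference of -2.13 at 0.5 µM copper.

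Low pH at 300 µM copper changed 8148 genes, 42.4% of those tested, with 3751 higher and 4397 lower at pH 3. Among changes of at least 2-fold 919 genes were higher and 516 lower, and among changes of at least 4-fold 236 were higher and 14 lower. With a pseudocount of 0.1, 1288 were higher and 1040 lower by at least 2-fold, a smaller imbalance (55.3% higher against 64.0%). Of the 1132 abundant genes, 353 were lower at pH 3, 246 higher and 533 not called. Genes moved by low pH at both copper levels comprised 1040 higher at both (501 for independent lists), 2199 lower at both (941) and 543 in opposite directions (1390), and across genes the differences correlated at r = 0.33.

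Low pH at 0.5 µM copper and copper at pH 4.8 were measured against the same 3 control libraries. They shared 1403 higher genes (653 for independent lists) and 1946 lower genes (1091), and 817 went in opposite directions (1727). Cs7g01050, Cs8g15220 and Cs5g06570 rose in both, by 2.73, 2.25 and 1.86 under low pH and by 5.11, 5.44 and 5.27 under copper, while Cs1g26375 fell in both. Across genes the differences correlated at r = 0.44, where unchanged groups simulated against shared controls gave 0.50. Their covariance was 0.134, against 0.013 to 0.016 in 100 simulations. With 3 controls that cannot be split into sets of at least 2, part of the excess in shared genes may come from the shared libraries.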

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

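The splits of the libraries were fixed before the results were seen; the other tests in this part were chosen after.

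Copper effects that differed between pH 3 and pH 4.8 in the interaction test draw attention first. They number 3991 genes, and 402 genes were called in opposite directions at both pH values. Cs4g02690 had an interaction of 8.21 and rose at pH 3 while it fell at pH 4.8. The fitted interaction of orange1.1t05521, 8.11, depends on the pseudocount (11.43 with 0.1) because the gene was listed at 0 in all 3 libraries at pH 4.8 with 300 µM copper, so only its direction is meaningful. Cs1g19920 had -3.15 and fell under copper at pH 3, and Cs7g01050 had -3.12 and rose more at pH 4.8. Of 100 splits of the libraries within each pH, 4 gave as many interaction genes, the real one included. This share cannot decide on chance for the interaction, since most splits mix copper levels and so move the copper effect into the spread. The median of the other splits was 0 genes. The highest other split, with 10971 genes, exchanges the copper levels at one pH only, so it measures the average copper effect and points to that structure of the samples. The other splits above the real count, with 6321 and 4941 genes, exchange all 6 libraries at pH 4.8 and 2 at pH 3, so they are not plain exchanges of the copper levels but lie close to the highest split. For each comparison between groups, 10 splits of the 6 libraries exist, too few for a share under 0.05: in each, 1 split, the real one, gave as many genes, with 6972, 9988, 6674 and 8148 genes against a highest other value of 0. Every other split mixes the groups compared and moves their difference into the spread. Their value of 0 was therefore close to fixed beforehand and gives no measure of chance.

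Copper changed more at pH 4.8 than at pH 3 (noise-corrected sizes of 0.682 and 0.531, a ratio of 1.28). The tables argue against the wider spread of the pH 3 libraries with 300 µM copper as the source, since the ratio was still 1.24 at its lowest, without replicate 2 of that group. They also argue against exchanged labels of the copper-treated groups as the source, since exchanging the labels would leave a ratio of 1.17. With a ratio above 1 either way, it does not show whether labels were exchanged. A candidate explanation is that low pH alone had already moved genes the way copper moved them at pH 4.8: the covariance of these differences exceeded that of shared libraries by 0.120, and the copper-treated pH 3 group lay farther from the pH 4.8 control (0.731) than the copper-treated pH 4.8 group did (0.682). The hypothesis does not say whether less copper injury or more came with either pH, which FPKM alone does not show.

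The 20 genes at 0.5 FPKM or less at pH 4.8 with 300 µM copper lie on 7 chromosomes and unplaced sequence, and among pools elsewhere 19 varied together (r over 0.8 with the mean of the others) while 1 went against them (-0.67). The median pairwise correlation of their deviations within groups was 0.93, against at most 0.39 in 10000 random sets of matched level, as a shared programme that the pools run to different extents would give for the 19. RNA of a single source of constant composition, mixed into the 9 other libraries, is argued against, since it would keep the genes at fixed ratios. The ratio of a gene to the others separated pH 3 with 300 µM copper from 0.5 µM copper for 8 of the 20 genes (4 higher, 4 lower). If the 9 libraries were exchangeable, 0.48 would do so, but those at 0.5 µM come from both pH values. Each gene enters the reference of the others, so rises and falls are linked and the 8 are not separate events. A source whose composition changed with copper could give both this count and the correlation of 0.93, and was not tested. Loci missing from the plants of that group cannot be told apart from silent genes, although 15 of the 20 were above 0 in at least 1 of its libraries: reads of similar copies elsewhere in the genome could be listed at a missing locus, and no sequence was used to look for such copies. An even share of reads carried over from other libraries would not give these values, since orange1.1t05521, at 146.59 to 487.49 FPKM elsewhere, was at 0.00 in all 3 libraries, while a gene at 6.48 to 17.87 FPKM elsewhere was at 0.20, 0.09 and 0.49.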

How the results depend on the processing

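Median scaling and, for the overlap, quantile normalization were chosen after seeing the data; the other alternatives were planned. Of 98 alternatives of the 6 counts of genes, 89 stayed within 1.5 times, and so did all 48 that left out a library. Requiring a log2 difference of at least 1 gave 1233 genes for copper at pH 3, 2136 for copper at pH 4.8, 637 and 1435 for low pH at 0.5 and 300 µM copper, 1405 for the interaction and 498 for the overlap. An adjusted p under 0.01 gave 4531 for copper at pH 3, 3850 for low pH at 0.5 µM and 2317 for the interaction. Both follow from the stricter threshold. Leaving out a library gave 5469 to 8015 genes for copper at pH 3 and 8563 to 9055 for copper at pH 4.8. The value of 8015, above the 6972 with all libraries, came without replicate 2 of pH 3 with 300 µM copper. The other omissions gave 5469 to 6452 for copper at pH 3. Quantile normalization moved the share of rises from 56.8% to 47.2% for copper at pH 3. The scalings moved the median difference of all genes by -0.088 to 0.054. The labels do not say that replicate numbers mark a shared origin, and only 7 of 18 same-numbered pairs had deviations correlated over 0.1 (-0.22 to 0.24, median 0.06, against -0.06 for other pairs), so the numbers were not taken as pairs. As a hint from the data, 7 of 12 libraries correlated best with their own number, where chance gives 4. With the replicate number as a block, 7125, 10098, 6847, 8326 and 4106 genes were called in the 5 tests and 4729 in the overlap. Fits to only the groups compared gave 5644 genes for copper at pH 3 and 10500 for copper at pH 4.8. Low pH then gave 7962 at 0.5 µM copper and 6487 at 300 µM. The order of the comparisons below copper at pH 4.8 therefore depended on the spread used. Each gene named by the fixed rule stayed called, in the same direction, in all 204 alternatives. The rule takes the largest called changes and, outside the interaction, only genes without overlap between groups. This outcome was therefore close to fixed by the selection. The camera and fry alternatives were not run, because the lists stayed empty, and DESeq2 and RLE factors were replaced by the alternatives planned for tables without counts. Depth limits values below about 0.132 to 0.169 FPKM on a gene of 1 kb.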

Other observations

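The rules and tests of this part were chosen after seeing the data. Several stretches of neighbouring genes changed together, counted as runs of at least 4 adjacent tested genes, each called and changed at least 2-fold in the same direction. Copper at pH 3 gave 8 runs, 7 of them higher, copper at pH 4.8 gave 9, also with 7 higher, and low pH at 300 µM copper gave 10, with 8 higher. The interaction gave 3 and low pH at 0.5 µM copper gave 0. In 1000 shuffled gene orders the highest numbers of runs were 2, 3, 2, 2 and 1 in the same order of tests. On chromosome 5, 4 genes between 24360056 and 24377606 summed to 14.0 ± 1.3 FPKM at pH 3 and 17.0 ± 5.3 at pH 4.8 with 0.5 µM copper (SD, n = 3 in each group), and to 907.6 ± 204.5 and 43.1 ± 9.2 with 300 µM. Another run on that chromosome, between 28503127 and 28618502, which holds Cs5g25760, summed to 1.5 ± 0.6 and 2.2 ± 0.7 FPKM at 0.5 µM and to 218.0 ± 63.7 at pH 3 and 10.9 ± 5.8 at pH 4.8 with 300 µM. A run of 7 genes on chromosome 9 (13887366 to 13976316) rose at pH 3 from 10.6 ± 0.7 to 77.4 ± 19.4 FPKM in sum. It stood at 10.2 ± 1.0 and 23.8 ± 4.1 FPKM without and with copper at pH 4.8.

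A further run from copper at pH 3 lay on chromosome 9, where 4 genes between 5838744 and 5845849 rose under copper at pH 3, from 74.0 ± 18.4 to 245.9 ± 42.4 FPKM in sum, and stood at 132.9 ± 33.7 and 27.4 ± 2.5 FPKM without and with copper at pH 4.8, where they made no run. On chromosome 8, 4 genes between 9371825 and 9418907 rose under copper at pH 4.8, from 27.2 ± 3.0 to 157.7 ± 25.3 FPKM in sum, and stood at 70.2 ± 7.7 and 138.8 ± 28.3 FPKM without and with copper at pH 3. On chromosome 2, 4 genes between 29930520 and 29947225 fell under copper at pH 4.8, from 599.6 ± 55.0 to 244.4 ± 9.8 FPKM in sum, and stood at 378.1 ± 19.1 and 256.2 ± 58.9 FPKM without and with copper at pH 3. Neither of these made a run under copper at pH 3, and the sums themselves were not tested.

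Adjacent pairs changed at least 2-fold in the same direction numbered 148 for copper at pH 3, where shuffled gene orders gave a mean of 40.7 and at most 59, and 243 for copper at pH 4.8, against 102.5 and at most 139. Low pH gave 38 pairs at 0.5 µM copper (at most 19 in shuffled orders) and 138 at 300 µM (at most 70). Reads shared by overlapping genes are argued against for copper at pH 3, where 0 of the 148 pairs were overlapping genes. Reads shared between near-identical tandem copies cannot be told apart from separate copies that changed together: 75.0% of the pairs lay on the same strand, against 51.9% of all adjacent pairs, and no sequence was used here to compare the copies.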
